A study of Mus musculus with 6 samples.

How the data were processed

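RNA from 6 mouse tumours was measured on Affymetrix whole-transcriptome arrays, 1 array per tumour. The tumours came from 3 mice, each of which gave a primary and a metastatic tumour, so that each group held 3 arrays. Groups were taken from the tissue label and the mouse from the donor label. Total RNA was extracted from fresh frozen tissue with a column kit and labelled with biotin, per the labels. For the primary tumour of mouse C2M3 the title and the donor label name C2M3, while the source name gives C2M2, and the donor label was followed. The 3 mice are separate animals, so the spread between arrays of a group includes the spread between animals.

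The values are on the log2 scale, per probe set, as deposited by the authors. The submitters' processing notes name RMA and Transcriptome Analysis Console, without versions. RMA corrects the background, applies quantile normalization to probe intensities and summarises probes into probe sets. The log2 values lay between 2.21 and 19.9 over the 6 arrays. They had not been centred per gene, and the array medians over the genes tested lay between 4.90 and 5.15. The genome build of the array annotation was not given in the sources used here, so no coordinates are printed. Scanner files were not used here.

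Of the non-control probe sets, 65956 in number, 30604 carried 1 gene symbol in the platform annotation, 2146 carried several and 33206 carried none there. A further 6732 control probe sets were left out. Symbols of 827 probe sets were updated through the Entrez Gene identifier with a RefSeq gene table of the mouse assembly GRCm38.p6, and 29837 of the final symbols were found in that table. Probe sets with several symbols were not named. This left out Foxp3, the lineage factor of regulatory T cells, which lay on such a probe set. Where a gene had more than 1 probe set (355 genes), the probe set with the highest mean over the 6 arrays was kept, which gave 30142 genes. No filter on dim genes was applied. Some genes belong to multi-copy families, and 610 genes had the same 6 values as another gene, so values of such genes cannot be assigned to 1 copy.

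Metastatic and primary tumours were compared with limma 3.58.1 in R 4.3.3, by a linear model with tissue as its only term and empirical Bayes moderation, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. Differences are metastatic minus primary on the log2 scale, with the moderated standard error (SE). The pairing of tumours by mouse follows from the donor label. The deviations of the 2 tumours of a mouse from their group means correlated across genes with r = -0.05 for mouse C1M3, 0.35 for C1M5 and 0.07 for C2M3, where the highest r with a tumour of another mouse was 0.13, -0.02 and 0.09. By this measure only C1M5 showed its pairing. Without group means removed, the primary tumour of C1M3 correlated most with the metastatic tumour of its own mouse (r = 0.980, against 0.956 to 0.973 with the other arrays). That metastatic tumour correlated most with the primary tumour of C1M5 (r = 0.984). A fit with the mouse as a block was the alternative.

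The design, the gene lists, the rule for named genes and most alternatives to each step were fixed before the data were examined. The 42 lists hold 610 distinct genes, of which 548 were measured, and cover ovary and neighbouring organs, fat, muscle, blood and immune cells, vessels, matrix, adhesion, proliferation, hypoxia and lipid metabolism. Some genes belong to more than 1 list. Lists with at least 5 measured genes were tested, 41 in all. The red blood cell list had 3 measured genes and was not tested. Each list was compared with all other genes by camera with a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were alternatives. The adjusted p "adjusted over the list alone" uses only the measured members of that list.

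Genes were named by a fixed rule. The first part takes up to 12 genes per direction with the largest difference among those past the threshold with the same sign in all 3 mice. Where fewer pass, it is filled with the largest differences among genes with the same sign in all 3 mice whose higher group had a mean above the median of all genes tested, given as values that did not pass. Predicted and clone-named genes, microRNAs, small nucleolar RNAs and antigen receptor segments were counted but not named. The second part takes up to 4 members per list with the largest difference. The third names Vegfa, Kdr, Msln, Wt1, Cd274, Cd3e, Cd8a and Mki67 in every case. Other members of a list were chosen as examples after their values were seen.

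The fit and the list test were tested on simulated data with the spread of the real genes, 3 arrays against 3 over 30142 genes, of which 100 were changed by 2-fold and 100 by 4-fold. The fit called 49% of the 2-fold and 77% of the 4-fold changes, with 11 unchanged genes called. With the simulated spread capped at its median these shares were 69% and 100%, with 7 unchanged genes called. The changed genes were drawn at random from all genes tested, whose real differences had a median SE of 0.135. The shares therefore do not apply to genes with a much wider SE, such as many of those named below. The simulated list with a log2 shift of 2 was called, and no unshifted list was. Genes were simulated independently of each other. The simulation therefore cannot show how often camera calls unshifted lists whose genes are correlated, as in the real lists.

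Alternatives covered the mouse as a fixed or random block, a further quantile normalization, centring of each array on its median, array weights, only genes above the median level, the mean of all probe sets of a gene, moderation with a trend, every non-control probe set, other thresholds, and leaving out each array or each mouse. With 3 arrays against 3 there are 10 splits, so an exact permutation test cannot give a p below 0.1. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. For arrays, precision is limited by their number.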

Results

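ID8 is a cell line derived from mouse ovarian surface epithelium, and ID8-VEGF is a variant of it made to produce vascular endothelial growth factor. The cells had been placed beneath the membrane that encloses the ovary, and the mice carried a primary tumour and metastatic tumours. Late tumours of 3 mice, named C1M3, C1M5 and C2M3, were profiled on whole-transcriptome arrays. Each mouse gave 1 primary and 1 metastatic tumour, so that 3 primary arrays were compared with 3 metastatic arrays. The work belongs to the development of an ovarian cancer model with surgical removal of the primary tumour, and the comparison asks how metastatic tumours differ in expression from primary tumours. Whether these 3 mice had surgery is not given in the labels. The 30142 genes tested had a median log2 intensity of 5.08, 4.90 and 4.90 in the primary tumours of mice C1M3, C1M5 and C2M3, and of 4.96, 5.08 and 5.15 in their metastatic tumours. The site of each metastatic tumour is not given in the labels. The number of arrays limits the precision of every value.

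The 6 tumours did not separate by tissue over all genes. The correlation across genes between arrays averaged 0.980 for pairs of metastatic tumours, 0.969 for pairs of primary tumours, 0.976 for the 2 tumours of a mouse and 0.974 for a primary and a metastatic tumour of different mice. These correlations are across genes, which are not independent replicates. Tissue held 19.15% of the total sum of squares, against 20% from its share of the degrees of freedom, and 6 of the 10 splits of the arrays into groups of 3 gave a share as large (exact permutation p = 0.6, where 0.1 is the smallest possible). Differences between mice held 42.24%, against 40% from their degrees of freedom. The primary tumour of mouse C1M3 was the array least like the other primary tumours, with r = 0.964 to C1M5 and 0.956 to C2M3, while those 2 correlated with r = 0.987.

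**Figure D1:**
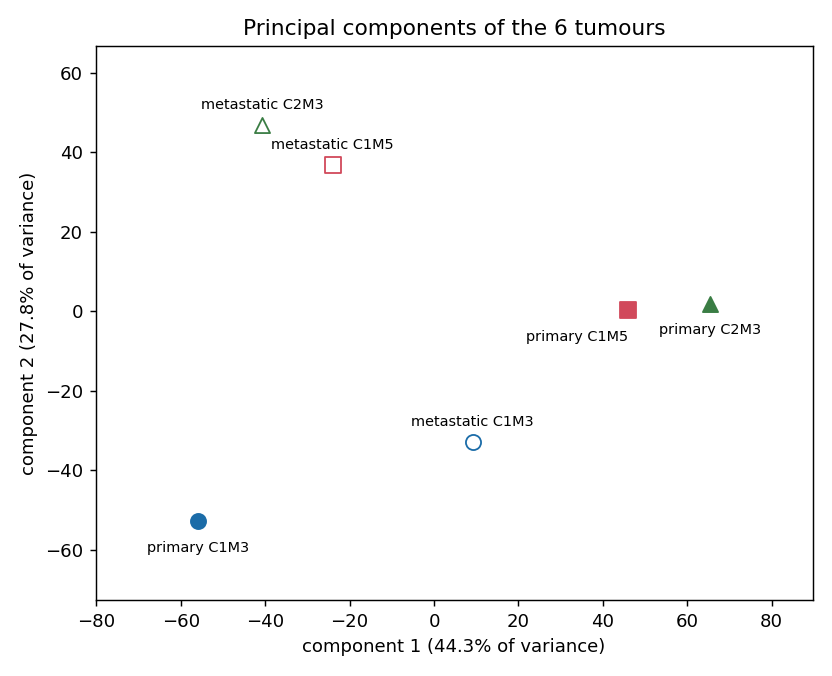
Principal components of the 6 tumours over 30142 genes, with component 1 (44.32% of the variance) on the x axis and component 2 (27.78%) on the y axis. Filled symbols are primary and open symbols metastatic tumours, with 1 shape and colour per mouse. The primary tumours of C1M5 and C2M3 lie together at component 1 scores of 46.0 and 65.4, and the primary tumour of C1M3 lies at -55.9.

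Among the gene lists, fat cell genes had the widest median difference between metastatic and primary tumours, with their highest values in the primary tumours of mice C1M5 and C2M3. Lipid uptake, cell cycle, cholesterol synthesis, hypoxia and smooth muscle genes also had lower mean values in metastatic tumours, and genes of antigen presentation on MHC class I and class II had higher ones. No gene passed the test. With limma, 0 of 30142 genes had an adjusted p under 0.05, and the smallest adjusted p was 0.407. At an unadjusted p under 0.05 there were 867 genes higher and 402 lower in metastatic tumours, 1269 in all, where chance alone gives about 1507. Olfactory and vomeronasal receptor genes, 1717 of the 30142 genes tested, made up 67 of the higher and 15 of the lower genes. MicroRNA genes, 602 of the genes tested, made up 78 and 11. Signal of the receptor genes was raised in the primary tumour of C1M3 and in the metastatic tumours of C1M5 and C2M3. The fit with the mouse as a block also gave 0 genes, with 891 higher and 594 lower at an unadjusted p under 0.05. A mean difference of at least 2-fold was found in 656 genes, 485 higher and 171 lower in metastatic tumours. The difference had the same sign in all 3 mice for 5946 genes, or 19.73%, against 25% by chance, and the 2 groups did not overlap for 2301 genes, or 7.63%, against 10% by chance. These chance shares assume no tied values. Ties between arrays occur among dim genes and count against a gene in both counts, so the true chance shares are lower.

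Among 41 gene lists, camera with its preset correlation placed 2 higher and 6 lower in metastatic tumours at an adjusted p under 0.05. All 8 of these calls were lost with an estimated correlation and by fry, whose smallest adjusted p was 0.752. No member of any list passed over all genes or when adjusted over the list alone.

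All 14 measured adipocyte genes had a lower mean in metastatic tumours, with a median difference of -2.0. The list ranked below other genes by camera (adjusted p = 7.1e-07), with adjusted p = 0.889 with an estimated correlation. The mean log2 intensity of the list was 8.58 ± 2.41 (SD, n = 3) in primary and 6.09 ± 0.21 in metastatic tumours. The primary tumours differed widely, with a list mean of 10.83 in C2M3, 8.87 in C1M5 and 6.04 in C1M3. The metastatic tumours had 5.85, 6.19 and 6.22 in the same order of mice. With 1 primary tumour per mouse, a difference between animals cannot be told from one between excised pieces or arrays. Adipoq, which encodes the fat cell hormone adiponectin, had log2 intensities of 13.21, 10.59 and 5.80 in the primary tumours of C2M3, C1M5 and C1M3 and of 5.75, 6.01 and 6.09 in their metastatic tumours, a mean difference of -3.92 (SE 1.95, adjusted p = 0.842). Retn, which encodes resistin, differed by -5.02 (SE 2.13), Car3, a carbonic anhydrase abundant in fat, by -4.20 (SE 1.86), and Cidec, a lipid droplet protein, by -3.64 (SE 1.74). Within mouse C1M3 the median difference of the list was 0.23, against -1.99 in C1M5 and -4.31 in C2M3. The median difference between the groups was -0.94 without the primary tumour of C2M3 and -3.06 without that of C1M3.

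The 15 measured genes of lipid uptake and fatty acid oxidation all had a lower mean in metastatic tumours, with a median difference of -0.60 (camera adjusted p = 4.92e-05, and adjusted p = 0.889 with an estimated correlation). The list followed the adipocyte list across arrays, with means of 8.14, 8.90 and 9.67 in the primary and 8.15, 7.70 and 7.93 in the metastatic tumours of C1M3, C1M5 and C2M3, and its median within those mice was 0.19, -0.77 and -1.19. Fabp4, a fatty acid carrier of fat cells that is also in the adipocyte list, differed by -3.50 (SE 1.86), and the fatty acid translocase Cd36 by -3.25 (SE 2.27). Within C1M3, C1M5 and C2M3 these were 0.58, -3.65 and -7.44 for Fabp4, and 1.52, -4.10 and -7.15 for Cd36. Pdk4, a kinase that restrains pyruvate use, differed by -1.5 (SE 0.32) and was lower in the metastatic tumour of every mouse, by 1.06, 2.02 and 1.43 in C1M3, C1M5 and C2M3. Its adjusted p was 0.842 over all genes. The call of this list was lost without the tumours of mouse C2M3 (adjusted p = 0.109).

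All 10 measured smooth muscle genes also had lower means in metastatic tumours, with a median difference of -0.68 (camera adjusted p = 0.00469, and adjusted p = 0.889 with an estimated correlation). The list mean was highest in the same primary tumours as the adipocyte list, 7.70 in C2M3 and 6.92 in C1M5, against 5.77 in C1M3 and 6.09 to 6.26 in metastatic tumours. Calponin, encoded by Cnn1, differed by -1.08 (SE 0.75), desmin, encoded by Des, by -1.06 (SE 0.53), and smooth muscle myosin heavy chain, encoded by Myh11, by -1.04 (SE 0.54). The median was -1.43 without the primary tumour of C1M3 and -0.11 without that of C2M3. The call was lost without the primary tumour of C2M3 (adjusted p = 0.485), with centring of each array on its median (median -0.78, adjusted p = 0.0842), with the receptor gene level of each array as a covariate (adjusted p = 0.0684), without the tumours of C1M5 (adjusted p = 0.0761) and without those of C2M3 (adjusted p = 0.553).

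All 13 measured genes of cholesterol and steroid precursor synthesis had a lower mean in metastatic tumours, with a median difference of -0.27 (camera adjusted p = 0.000195, and adjusted p = 0.889 with an estimated correlation). The list mean was 7.96 ± 0.26 (SD, n = 3) in primary and 7.55 ± 0.45 in metastatic tumours, and the lowest array was the metastatic tumour of C2M3 at 7.03. Sqle, which encodes squalene epoxidase, differed by -0.75 (SE 0.82), the transcription factor gene Srebf2 by -0.70 (SE 0.46), Hmgcs1 by -0.68 (SE 0.38), and Fdft1, which encodes squalene synthase, by -0.66 (SE 0.24). With limma each had an adjusted p of 0.842 or above. The median of the list was -0.13 without the metastatic tumour of C2M3, -0.47 without the primary tumour of C2M3, -0.44 without the metastatic tumour of C1M3 and -0.43 without that of C1M5.

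All 21 measured cell cycle genes had a lower mean in metastatic tumours, with a median difference of -0.52 (camera adjusted p = 0.000419, and adjusted p = 0.889 with an estimated correlation). Their list mean was 9.36 in the primary tumour of C1M3, 7.98 in that of C1M5 and 7.80 in that of C2M3, and 8.24, 8.08 and 7.23 in the metastatic tumours. Mki67, the proliferation marker Ki-67, had log2 intensities of 11.83 ± 0.94 (SD, n = 3) in primary and 10.86 ± 1.45 in metastatic tumours, a difference of -0.97 (SE 0.90). The mitotic kinase Plk1 differed by -0.97 (SE 0.67) and Cdc20, an activator of the anaphase-promoting complex, by -0.91 (SE 0.69). Without the primary tumour of C1M3 the call was lost (adjusted p = 0.44) and the median difference was -0.00, and it was also lost without the metastatic tumour of C2M3 (median -0.22, adjusted p = 0.154) and with array weights (adjusted p = 0.167). The primary tumour of C1M3 had the lowest mean of all arrays for 11 of 14 lists of host cells, among them macrophage genes at 6.08, against 7.32 to 8.27 in the other arrays, the exceptions being the mast cell, the cytotoxic T and NK cell and the adipocyte lists.

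Of 19 measured genes of hypoxia and glycolysis, 18 had a lower mean in metastatic tumours, with a median difference of -0.43 (camera adjusted p = 0.012, and adjusted p = 0.889 with an estimated correlation). Adm, which encodes the vasodilator peptide adrenomedullin, differed by -2.50 (SE 0.64, adjusted p = 0.842) and was lower in the metastatic tumour of every mouse, by 1.34, 2.0 and 4.14. The glucose transporter gene Slc2a1 differed by -0.97 (SE 1.68) and ranged from 14.40 in the primary tumour of C1M3 to 8.43 in the metastatic tumour of C2M3. The list mean was 10.04, 8.97 and 8.16 in the primary and 9.12, 8.99 and 7.29 in the metastatic tumours of C1M3, C1M5 and C2M3. Without the primary tumour of C1M3 the call was lost (adjusted p = 0.412) and the median difference was 0.12, and it was also lost without the metastatic tumour of C2M3 (median 0.06, adjusted p = 0.537), without both tumours of C1M3 (adjusted p = 0.0701), with centring of each array (median -0.53, adjusted p = 0.21) and with array weights (median -0.08, adjusted p = 0.167). The median was -0.87 without the primary tumour of C2M3 and -0.65 without the metastatic tumour of either C1M3 or C1M5.

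Antigen presentation genes had higher means in metastatic tumours. All 9 measured genes of the MHC class II list did, with a median difference of 0.70 (camera adjusted p = 0.0194, and adjusted p = 0.889 with an estimated correlation), as did all 12 of the MHC class I list, with a median of 0.36 (camera adjusted p = 0.0265, and adjusted p = 0.889 with an estimated correlation). The class II genes H2-Eb1 and H2-Ab1 differed by 1.11 (SE 0.82) and 1.0 (SE 0.72), and Ctss, which encodes the invariant chain protease cathepsin S, by 1.4 (SE 0.58), or 0.88 without the primary tumour of C1M3. Among class I genes, B2m, the light chain of class I molecules, differed by 0.89 (SE 0.74), H2-K1 by 0.66 (SE 0.47) and the peptide transporter gene Tap1 by 0.50 (SE 0.32). Within C1M3, C1M5 and C2M3 these were 2.76, -0.11 and 0.03 for B2m, 1.63, 0.24 and 0.11 for H2-K1, and 1.47, -0.05 and 0.07 for Tap1. The difference was widest in mouse C1M3, with within-mouse medians of 1.43 for class II and 0.87 for class I, against -0.02 and 0.03 in C1M5 and 0.47 and 0.11 in C2M3. Both calls were lost without the primary tumour of C1M3 (adjusted p = 0.532 for class II and 0.988 for class I), without the metastatic tumour of C1M3 (0.181 and 0.0636), without both (0.897 and 0.897), without the metastatic tumour of C2M3 (0.167 and 0.154) and with array weights (0.288 and 0.515), and the class II call without the primary tumour of C1M5 (adjusted p = 0.123). Without the primary tumour of C1M3 the medians were 0.34 for class II and 0.10 for class I, and the class II median was 0.46 without the metastatic tumour of C2M3 and 1.09 without that of C1M5. In the primary tumour of C1M3 11 of 14 host cell lists had their lowest mean.

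**Figure D2:**
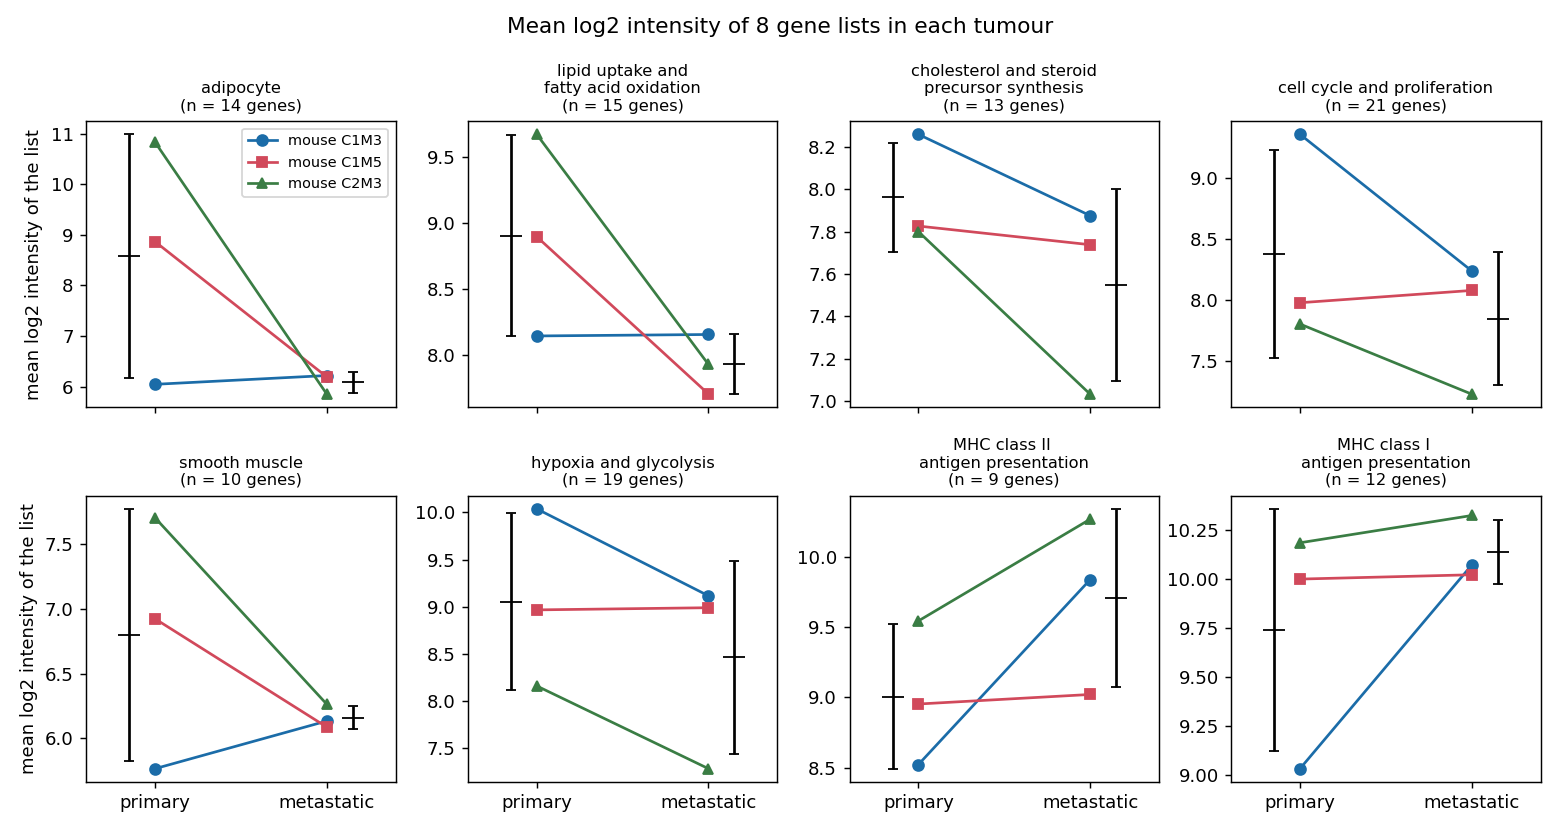
Mean log2 intensity (y axis, a separate scale per panel) of the 8 gene lists placed higher or lower by camera, in the primary and metastatic tumour of each mouse (x axis). Coloured symbols joined by lines are the 2 tumours of a mouse, and black marks are the group mean ± SD (n = 3). The adipocyte mean goes from 8.87 to 6.19 in C1M5 and from 10.83 to 5.85 in C2M3, and from 6.04 to 6.22 in C1M3.

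With the mouse as a block, 3 further lists passed in camera. The ovarian granulosa, theca and luteal cell list lay lower in metastatic tumours (blocked adjusted p = 0.00494, against 0.063 without the block), with 11 of 17 measured genes negative and a median of -0.22. Among them Star, which delivers cholesterol for steroid synthesis, differed by -0.31 (SE 0.14) and Inha, the inhibin alpha subunit gene, by -1.42 (SE 1.82). The mean difference of Inha rests on the metastatic tumour of C1M5: its within-mouse differences were -0.52, -3.32 and -0.43 in C1M3, C1M5 and C2M3. The mast cell list lay lower (blocked adjusted p = 0.0274, against 0.386), with Mcpt4, a mast cell protease gene, at -0.98 (SE 0.65). The type I interferon list lay higher (blocked adjusted p = 0.0194, against 0.0637), with 13 of 18 genes positive, among them Xaf1 at 0.47 (SE 0.17) and Ifit1 at 0.48 (SE 0.26), while Rsad2 lay at -0.71 (SE 0.70). With an estimated correlation and the block each of the 3 had an adjusted p = 0.711. Without the block, leaving out the primary tumour of C1M5 brought the ovarian median to -0.01 (adjusted p = 0.278), leaving out single arrays moved the mast cell median between -0.76 (without the metastatic tumour of C2M3) and 0.03 (without that of C1M3), and the interferon median was 0.05 without the primary tumour of C1M3 (adjusted p = 0.664). Some settings without the block also called 2 of these lists in camera. The ovarian list passed downward among genes above the median level (adjusted p = 0.0165), with array weights (0.0173), and without the primary tumour of C1M3 (0.0148) or both its tumours. The interferon list passed upward with centring (0.0487), with the receptor covariate, without the primary tumour of C2M3, without the metastatic tumour of C1M5, and without mouse C1M5 or C2M3.

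The single genes with the widest differences of 1 sign in all 3 mice did not pass the test. On the lower side, Cyp2e1, a cytochrome P450 of liver and fat (Entrez Gene 13106), differed by -6.61 (SE 2.47), with values of -0.48, -9.14 and -10.22 in C1M3, C1M5 and C2M3. The lipogenic factor gene Thrsp differed by -3.37 (SE 1.79), Pcx, which encodes pyruvate carboxylase, by -2.76 (SE 1.12), the catalase gene Cat by -2.42 (SE 0.91), the growth hormone receptor gene Ghr by -1.97 (SE 0.79) and Fam13a by -2.01 (SE 0.95). For each of these the difference within C1M3 was between -0.48 and -0.03, and it was widest in C2M3. There Thrsp differed by -7.215, against -2.86 in C1M5, and Pcx by -5.31, against -2.75. Defb19, a beta-defensin gene, differed by -2.79 (SE 1.48), the homeobox gene Rhox8 by -2.20 (SE 0.75), the pancreatic elastase gene Cela3b by -2.03 (SE 1.20), Myl9, a myosin light chain gene of smooth muscle, by -1.99 (SE 1.08), with -3.15, -1.59 and -1.23 in C1M3, C1M5 and C2M3, and Tmem114 by -1.97 (SE 1.26). All had an adjusted p of 0.842 in limma.

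No common theme was tested among the genes on the higher side. Cx3cr1, the fractalkine receptor of monocytes and macrophages (Entrez Gene 13051), differed by 1.65 (SE 0.66), with 2.53, 0.58 and 1.84 in C1M3, C1M5 and C2M3. The macrophage gene Mpeg1 differed by 1.61 (SE 0.96), the survival gene Bcl2a1a by 1.44 (SE 1.06) and the chemokine receptor gene Cxcr4 by 1.24 (SE 0.92). The macrophage list as a whole did not pass in camera (adjusted p = 0.474, and adjusted p = 0.925 with an estimated correlation), and without the primary tumour of C1M3 its median turned from 0.32 to -0.24 (adjusted p = 0.0203). The glutathione transferase gene Gstp3 differed by 1.78 (SE 1.33), Mal2, a gene of epithelial membrane traffic, by 1.67 (SE 1.85), Tmem255a by 1.44 (SE 1.22), Pdlim1 by 1.43 (SE 0.73), Gpr31b by 1.31 (SE 0.34) and Krtap5-1 by 1.22 (SE 0.34). Btbd35f14 differed by 2.28 (SE 0.70) and belongs to a family of near-identical copies, so its value is not assigned to 1 copy. Adjusted p values were 0.842, and 0.845 for Mal2. The differences without the primary tumour of C1M3 were 1.02 for Cx3cr1, 0.65 for Mpeg1, 0.34 for Bcl2a1a, 0.45 for Cxcr4, 0.57 for Gstp3, 0.83 for Mal2, 0.27 for Tmem255a and 0.81 for Pdlim1, while Gpr31b, Krtap5-1 and Btbd35f14 lay at 1.47, 1.41 and 2.26.

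**Figure D3:**
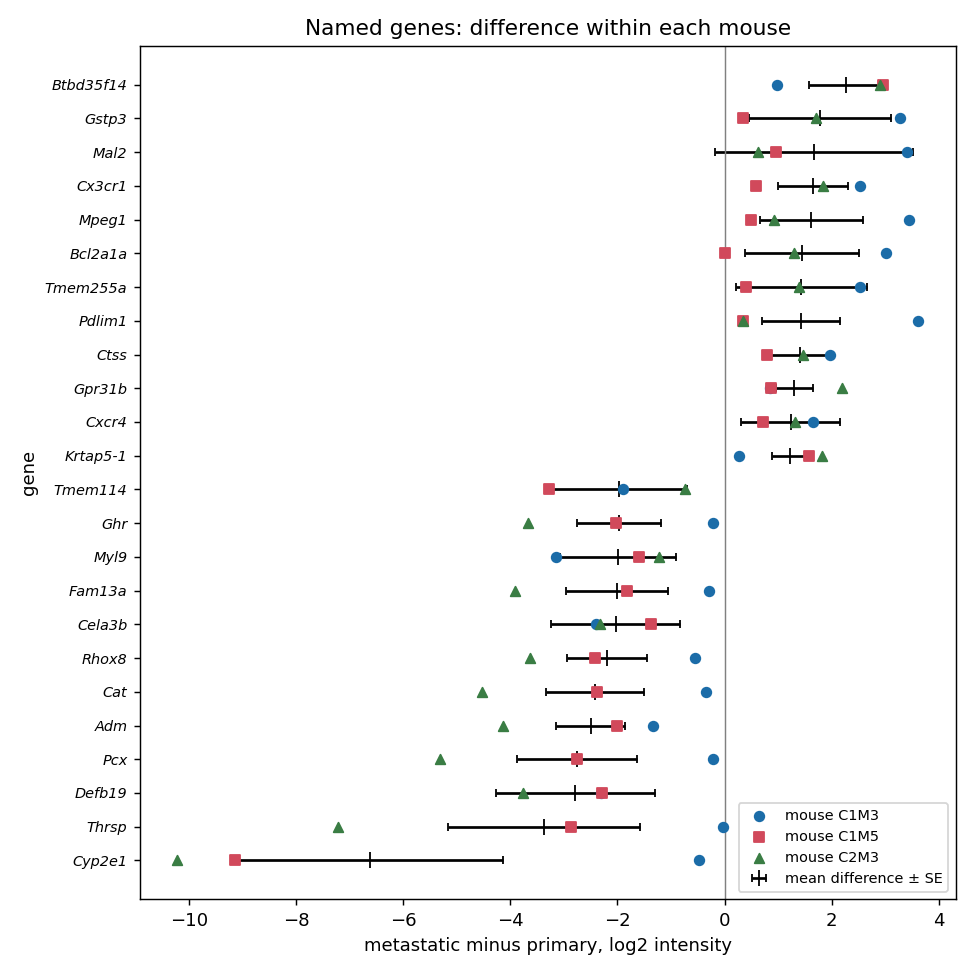
Difference between metastatic and primary tumour (x axis, log2 intensity) for the 12 genes per direction named by the rule on single genes (y axis), with 1 coloured symbol per mouse and the mean difference ± SE in black. The differences of Cyp2e1, Thrsp and Pcx lie far from 0 in C1M5 and C2M3 and near 0 in C1M3, where Cyp2e1 lies at -0.48.

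Genes tied to the model and to immune infiltration are given whatever their difference. Vegfa, whose product the cell line was made to secrete (Entrez Gene 22339), had log2 intensities of 14.00 ± 1.04 (SD, n = 3) in primary and 12.92 ± 2.48 in metastatic tumours, a difference of -1.08 (SE 1.39). Its lowest value was 10.06, in the metastatic tumour of C2M3, and all other arrays had at least 12.92. The metastatic tumours of C1M3 and C1M5, at 14.505 and 14.20, lay above the primary mean. The sign of the difference between group means therefore rests on the metastatic tumour of C2M3. Within C1M3, C1M5 and C2M3 the differences of Vegfa were -0.49, 0.10 and -2.86. The arrays do not separate the introduced from the native transcript here. The VEGF receptor gene Kdr differed by -0.55 (SE 0.89), Msln, which encodes mesothelin, by -0.06 (SE 1.5), and the mesothelial and ovarian surface marker Wt1 by -0.04 (SE 0.29). For Kdr the sign differed between mice, with 1.54, -1.63 and -1.55 in C1M3, C1M5 and C2M3. The highest Kdr value was 9.27, in the primary tumour of C2M3, against 7.16 and 7.72 in the primary tumours of C1M3 and C1M5. Cd274, which encodes PD-L1, differed by 0.14 (SE 0.07), the T cell genes Cd3e and Cd8a by 0.52 (SE 0.37) and 0.06 (SE 0.05). These immune genes were dim. Cd8a lay at 4.09 to 4.20, under the median of the negative controls of every array (4.635 to 4.895). Cd3e, at 4.29 to 5.84, and Cd274, at 4.97 to 5.25, lay under the 95th percentile of the negative controls (8.04 to 8.79). Their small differences are therefore near the floor. None of the genes in this paragraph had an adjusted p under 0.842.

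The other lists did not pass in camera without the block. Immune lists had small positive medians: dendritic cell 0.13 (adjusted p = 0.111), regulatory T cell 0.09 (0.206), immune checkpoint 0.13 (0.206), cytotoxic T and NK cell 0.11 (0.386), stromal and lymphoid chemokines 0.07 (0.386), inflammatory cytokines and acute phase 0.06 (0.386), B cell 0.11 (0.425), macrophage 0.32 (0.474), T cell 0.02 (0.759) and plasma cell 0.03 (0.977), with complement at -0.07 (0.386). The T cell, regulatory T cell, cytotoxic T and NK cell and B cell lists had group means of 4.56 to 4.95. These lie near the medians of the negative controls (4.635 to 4.895), which were higher in the metastatic tumour of every mouse. Differences of these lists are therefore near the floor. When the primary tumour of C2M3 was left out, the dendritic cell, B cell, immune checkpoint and macrophage lists passed upward at 0.22 (adjusted p = 0.00352), 0.22 (0.024), 0.20 (0.0202) and 0.81 (0.00348), and without the metastatic tumour of C1M5 the dendritic and regulatory T cell lists did at 0.14 (0.00725) and 0.15 (0.0179). With the primary tumour of C1M3 left out, the complement, mesenchymal and immediate early lists passed downward at -0.52 (adjusted p = 0.000157), -0.11 (0.00555) and -0.09 (0.0133). Vessel and matrix lists had negative or near-zero medians: endothelial cell -0.37 (adjusted p = 0.112), lymphatic endothelium -0.28 (0.112), basement membrane and matrix enzymes -0.09 (0.417), fibroblast and extracellular matrix -0.06 (0.425), and VEGF and angiogenic factors 0.09 (0.977). Without the primary tumour of C1M3 the endothelial, lymphatic, basement membrane and fibroblast lists passed at -0.84 (adjusted p = 0.00025), -0.63 (6.46e-05), -0.37 (0.00025) and -0.38 (0.000124), while without the primary tumour of C2M3 their medians were 0.10, -0.17, 0.06 and 0.22. Epithelial adhesion lay at -0.02 (adjusted p = 0.112, and 0.00694 at -0.09 without the metastatic tumour of C1M5), mesenchymal transition at -0.07 (0.628), ovarian cancer and p53 pathway at -0.06 (0.227) and mesothelial and ovarian surface epithelial genes at 0.13 (0.977, and 0.143 at -0.14 without the primary tumour of C1M3). Among lists of other tissues, pancreatic acinar cell lay at 0.05 (adjusted p = 0.503), oocyte at 0.01 (0.633), uterine epithelium at -0.03 (0.68), oviduct and ciliated epithelium at 0.01 (0.759), pancreatic islet at 0.01 (0.759), hepatocyte at 0.01 (0.977), intestinal epithelium at 0.00 (0.977) and skeletal muscle at 0.01 (0.977). Immediate early and dissection stress genes lay at 0.00 (adjusted p = 0.386) and monocyte and neutrophil genes at 0.03 (0.583). The mean and the median differed in sign for the pancreatic acinar, hepatocyte, mesenchymal and immediate early lists, with means of -0.20, -0.46, 0.03 and -0.07. Camera ranked 8 lists downward although their median was not negative, namely the monocyte and neutrophil, oviduct, intestinal, skeletal muscle, hepatocyte, mesothelial, VEGF and immediate early lists.

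Single members of these lists with wider differences also did not pass the test. The fibroblast gene Dpt, which encodes dermatopontin, differed by -2.14 (SE 2.23), with 2.53, -3.23 and -5.72 in C1M3, C1M5 and C2M3, and the red cell gene Alas2, which starts haem synthesis, by -2.27 (SE 1.56), with 0.76, -1.75 and -5.82. These were, without the primary tumour of C2M3, -0.29 for Dpt and -0.76 for Alas2. The pancreatic lectin gene Zg16 differed by -1.67 (SE 1.13), with -3.71 in C2M3. The macrophage gene Adgre1, which encodes a surface receptor of mature macrophages, differed by 1.03 (SE 0.90), with 2.36, 0.00 and 0.72 in the 3 mice, while Lyve1, found on lymphatic vessels and some tissue macrophages, differed by -0.99 (SE 0.69), with 0.06 in C1M3. The chemokine gene Cxcl9 differed by 1.11 (SE 0.87), with 2.58 in C1M3, and Apln, an endothelial tip cell peptide gene, by 1.07 (SE 0.94), with -0.61 in C1M3. Nkg7, a granule gene of cytotoxic cells, differed by 0.82 (SE 0.27) and S100a8, a neutrophil gene, by -0.40 (SE 0.10). Nkg7, at 5.38 to 6.74, and S100a8, at 4.51 to 5.18, lay under the 95th percentile of the negative controls (8.04 to 8.79).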

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

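The alternatives with identical values counted once, with the receptor gene level as a covariate, and with the replicate block plus an estimated correlation were chosen after seeing the data, and all others were planned. No alternative with an adjusted p under 0.05 or under 0.1 called a gene, the replicate block included, and over these the smallest adjusted p was 0.174, without mouse C1M3. Over every non-control probe set, 0 of 65956 passed. An unadjusted p under 0.05 with a 2-fold difference gave 57 genes higher and 21 lower in metastatic tumours. Gene lists moved more than genes. Against 2 higher and 6 lower as reported, an estimated correlation gave 0 and 0, fry 0 and 0, an estimated correlation with the replicate block 0 and 0, and array weights, which gave the primary tumour of C1M3 a weight of 0.264, 0 and 10. The correlation estimated within the called lists was 0.272 to 0.948, against the preset 0.01. The replicate block gave 3 and 8 lists and changed no other call. Leaving out 1 array or 1 mouse at a time gave 0 to 7 lists higher and 4 to 13 lower. Without the primary tumour of C1M3 there were 0 and 13, 9 of them new, and the macrophage list reversed to a median of -0.24 (adjusted p = 0.0203, from 0.32 with 0.474), although without the primary tumour of C2M3 it passed upward at 0.81 (adjusted p = 0.00348). The adipocyte and cholesterol lists passed in each setting run for lists except the estimated correlation, with or without the block, and fry, and neither moderation with a trend nor every probe set was run for lists. Centring each array on its median shifted the median difference of all genes from 0.02 to -0.09 and gave 3 and 4 lists. Of 188 named genes, the sign differed for up to 19, without the primary tumour of C1M3, and for 4 with centring. The causes of these shifts were not tested. Signal over background was lower in the metastatic tumour of every mouse: the median of positive minus negative controls was 5.38, 5.39 and 5.13 in the primary and 5.06, 5.23 and 4.94 in the metastatic tumours of C1M3, C1M5 and C2M3, and the share of genes above the 95th percentile of the negative controls 16.5%, 17.05% and 15.03% against 12.22%, 15.61% and 14.06%. This shift goes with tissue, so its part in the differences of dim genes cannot be separated.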

Other observations

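In this part the counts of splits, the test of further fat cell genes, the scaling test and the test on Y-linked genes were set before their results were seen, and the other tests were chosen after. Some differences followed the mouse and not the tissue. Immunoglobulin variable segments (199 genes) had median log2 intensities of 4.98 and 4.81 in the primary and metastatic tumour of C1M3, against 6.66 and 7.41 in C1M5 and 7.07 and 6.97 in C2M3. Jchain, which joins secreted IgA and IgM, had 5.39 and 5.14 in the tumours of C1M3, against 9.22 to 11.13 in the other 4 arrays. Msln lay at 10.91 and 11.12 in the tumours of C1M5, against 7.15 to 8.02 elsewhere, and the keratin gene Krt19 at 16.11 and 16.65, against 13.40 to 14.34. These mouse differences were noticed in the data and not tested.

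Other splits of the 6 arrays bear on the counts of calls. The split by tissue gave 0 genes, which all 10 splits match whatever the data, so this count decides nothing, and the highest other split gave 220. For lists, 8 of the 10 splits gave at least the 8 lists of the tissue split, and the highest other split gave 25. With 10 splits a share under 0.05 cannot be reached. Of the 4 splits that part all mouse pairs, the 3 others gave up to 220 genes and 5 to 15 lists, while the 6 that keep 1 pair together gave 0 genes and 0 to 25 lists. The split with 220 genes points to a structure of the samples, taken up last.

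Adipocyte genes were high in the primary tumours of C1M5 and C2M3 and low in the other 4 arrays. The highest metastatic list mean was 6.22 and the lowest primary one 6.04, in C1M3, and neither value decides on exchanged labels or on growth at the primary site: labels exchanged in both C1M5 and C2M3 would give the same values, and the exception in site rests on 1 array. Fat tissue in the excised piece is a candidate explanation that stays open: of 11 measured further fat cell genes, 8 were higher in both arrays than in each of the other 4, where at least 9 had been set as the mark, and Acly, Elovl6 and Me1 were the exceptions. Abundant fat cell transcripts were at high levels there, with Retn at 12.89 and 15.09 and Adipoq at 10.59 and 13.21, and 1 list gene, Fabp4, is shared with the lipid list. Fat around the ovary within the growing tumour and fat taken along at surgery cannot be told apart with these data.

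The primary tumour of C1M3 had high cell cycle and hypoxia genes and low host genes. Against the mean of the other 5 arrays its cell cycle genes lay higher by a median of 1.53 (21 of 21 highest there) and its hypoxia genes by 1.49 (16 of 19 highest there). A higher share of tumour cells as the whole cause stays open. The mesothelial and ovarian surface epithelial list had an upper quartile of differences of -0.02, but it also marks host mesothelium and followed the mouse. Its primary and metastatic means were 9.72 and 9.81 in C1M3, 11.33 and 11.54 in C1M5, and 10.55 and 10.625 in C2M3. A comparison with arrays of other mice therefore cannot decide. The median of the negative controls, 4.635, was the lowest of the 6 arrays, but these values had already been background-corrected and normalized. Whether the background signal of the primary tumour of C1M3 was raised therefore cannot be decided from them. The median of the olfactory and vomeronasal receptor genes was the highest of the 6 arrays there, at 4.35. A lower share of host cells stays open: 11 of 14 host cell lists had their lowest mean there, which restates the pattern, and the mast cell, cytotoxic T and NK cell and adipocyte lists did not. Among the 11, the T cell and B cell lists lay under the median of the negative controls there, so their ranks are near the floor. Whether division or oxygen supply differed in that tumour was not tested, nor was any biological explanation, since the labels set this tumour apart in no way.

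Olfactory and vomeronasal receptor genes (1717 genes) had median log2 intensities of 4.35, 4.16 and 4.29 in the primary tumour of C1M3 and the metastatic tumours of C1M5 and C2M3, against 3.92 to 4.01 in the other 3 arrays, and the split that follows these arrays called 220 genes, 218 higher in them, of which calls 23 were receptor genes, 169 had predicted names (76.8%, against 25.5% of all genes tested) and 61 were among the 275 genes that share values with at least 4 others. Scaling of whole arrays as the whole cause is argued against: after centring 197 of the 220 were still called in the same direction, among 375 calls of which 356 were higher in these arrays, and after quantile normalization 195 were, among 251. Tissue does not order the arrays, with 4.35 in the primary and 4.01 in the metastatic tumour of C1M3, but the pattern was defined by these arrays, so a part for tissue in the other 2 mice stays open. Genomic DNA of the female mice carried along in the RNA stays open too: the medians of 72 Y-linked genes, absent from such DNA, ranged over 0.13, against 0.43 for receptor genes and 1.59 for multi-copy genes, and their 95th percentiles were 4.80, 5.15 and 4.80 in the 3 arrays, against 4.64 to 4.82 in the others, while 602 microRNA genes had medians that ranged over 0.16 and 95th percentiles of 10.51, 10.26 and 10.82, against 8.53 to 9.48. A scan or hybridisation batch and RNA quality could give a like pattern, and no date in the labels allows a test.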
